A study of Mus musculus with 6 samples.

How the data were processed

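RNA from 6 cultures of GC1-Spg cells was measured, 3 after scrambled siRNA and 3 after mrhl siRNA, each on its own 1-colour Affymetrix array. Groups and replicate numbers were taken from the sample titles, which call the replicates biological. The deposited values are log2 expression values with a single value per probe set and array. Per the submitters' processing notes, GCOS and PLIER were used; versions, settings, background correction and normalization between arrays are not given in the sources used here. The log2 scale was read from the range of the values, which includes negative values. The test had been laid out for linear values as well, with an offset of 16 before taking logs, which the deposited log2 values did not need. The array medians differed by at most 0.11, so the values were used as deposited, without a further normalization.

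The value table held 45101 rows, of which 64 control rows were left out of the tests. The probe table paired 34945 of the other 45037 probe sets with exactly 1 gene symbol and 932 with several, and it did not list 9160. Of the 34945, 34741 had a gene ID found in the mouse gene table of assembly GRCm38.p6, and 0 symbols were updated. No gene was named from a probe set paired with several symbols. Neighbours of Phkb were taken from the order of genes in that assembly. Probe sets with a mean log2 value under the 25th percentile, 3.62, were left out, which left 33778. A gene was read through its tested probe set with the highest mean among those paired with it alone, and its adjusted p was that of the fit over all probe sets.

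The groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, as mrhl siRNA minus scrambled siRNA, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Of 33 gene lists, the 32 with at least 5 tested members were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry were run beside it. Each of the 3 compares different things: camera sets a list against the other genes, and fry asks whether its members move on balance in a single direction, or in its other form in either direction. Intervals are 95% intervals of the limma fit. Control rows were compared with two-sided exact permutation tests. Figures were drawn with matplotlib 3.10.9.

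The groups share replicate numbers, and whether these pair the arrays was checked by correlating deviations from the group means across probe sets. The correlations of equal numbers were 0.534, 0.201 and 0.567, all above the limit of 0.1 set beforehand, and those of unequal numbers ran from -0.518 to 0.0684. The numbers were therefore read as pairs, as the design text's 3 independent experiments allow. For number 2 the evidence is weak. Its 2 arrays correlated at 0.98, against 0.9836 for scrambled siRNA replicates 2 and 3 and 0.9833 for mrhl siRNA replicates 1 and 2. Deviations from a mean of 3 arrays sum to 0, so a shift in number 1 alone can also raise the other equal-number correlations. The blocked fit gave 0 probe sets past the threshold (limma, smallest adjusted p = 0.213) and 3411 at an unadjusted p under 0.05, and it stands beside a result where it changed a call or a count by over 1.5 times.

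The tests, the lists, the filter and the following rule for named genes were fixed before the data were examined. The 12 genes with the largest increase and the 12 with the largest decrease were to be named among those past the threshold whose groups do not overlap, filled by smallest p where fewer passed, without clone-type symbols. Because no gene passed, all 24 were filled by smallest p. Up to 4 passing members of each list were to be named, or the 2 with the smallest p where none passed. Phkb, Ddx5, Ddx17, Ctnnb1, Axin2, Myc, Ccnd1 and Sox8 were always to be named.

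Alternatives fixed beforehand were an offset of 1 or 64, quantile normalization, array medians set to 0, no filter or a filter at the median level, the replicate block, a trended and robust variance model, array weights, each array left out in turn, the mean of a gene's probe sets, a count of probe sets whose groups do not overlap, and a test without shared spread. Alternatives added after seeing the data were an offset of 16, the block with the trended and robust model or with the offset of 64, both arrays of number 1 left out, the 18S signal as a covariate, further forms of fry, and counts at an unadjusted p.

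The fits were tested on simulated data with 33778 probe sets, of which 100 were changed by 2-fold and 100 by 4-fold. Noise was drawn independently for each probe set. Pair effects were the blocked fit's estimates, which hold noise of their own, shuffled over probe sets. With pair effects, the unblocked fit recovered 74% of the 4-fold and 3% of the 2-fold changes with 0 false calls, and the blocked fit 82% and 4% with 3 false calls. Without pair effects, the unblocked fit recovered 88% and 20% with 6 false calls and the blocked fit 57% and 0% with 5. Noise was drawn at the spread of the unblocked fit for arrays without pair effects and of the blocked fit for those with them. The simulations thus differ in noise as well as in pair effects. All these shares hold for the numbers of changed probe sets given, since the adjustment is stricter where fewer change. In the list test, on 14885 genes, a list shifted by 0.3 was recovered (limma camera, adjusted p = 8.81e-22) and 0 unshifted lists were called. That test drew noise independently for each gene and added no pair effects. It does not show how often lists are recovered or wrongly called on these arrays, where other splits of the arrays called up to 9.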

Results

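Gene expression was measured in GC1-Spg, an established mouse cell line derived from spermatogonia, the mitotic germ cells of the testis. Cells were transfected with 100 nM of a scrambled siRNA, the control, or of siRNA against mrhl, and RNA was taken 44 h later. The noncoding RNA mrhl is transcribed from within an intron of Phkb, the gene of the beta subunit of phosphorylase kinase. Each group held 3 biological replicates, and each replicate was hybridized to its own 1-colour Affymetrix array with biotin-labelled cRNA. The deposited values were on the log2 scale, and the array medians differed by at most 0.11. Of 45037 probe sets that were not controls, 33778 were bright enough to be tested, and 14885 genes were each read through their brightest probe set. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.192. With the replicate number as a block it was 0.132. Standard errors and intervals of single genes below are from the fit without the block, so they also hold differences between pairs.

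The comparison asks which transcripts differ in level when mrhl is silenced. The silenced RNA itself could not be read, because no probe set was paired with mrhl in the probe table used here, and the quantitative PCR named in the design text was not analysed here. Its host gene Phkb was represented by a single tested probe set, with a log2 level of 7.62 ± 0.06 (SD, n = 3) after scrambled siRNA and 7.37 ± 0.01 (SD, n = 3) after mrhl siRNA. The log2 fold change of Phkb was -0.25 (SE 0.129, 95% interval -0.55 to 0.05), which did not pass the test (limma, adjusted p = 0.965). A probe set for the Phkb transcript does not check the silencing of mrhl.

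The highest-ranked difference was in Col3a1, the gene of the alpha-1 chain of type III collagen. Its log2 level was 5.85 ± 0.36 (SD, n = 3) in the controls and 7.89 ± 0.34 (SD, n = 3) after mrhl siRNA, a 4.11-fold difference. The differences within pairs of equal replicate number were 2.02, 2.12 and 1.99, so Col3a1 was higher after mrhl siRNA in 3 of 3 pairs. The log2 fold change was 2.04 (SE 0.244, 95% interval 1.47 to 2.61), and it did not pass the adjustment over all probe sets (limma, adjusted p = 0.965). With the replicate number as a block the adjusted p was 0.213 (limma). With that block and a trended, robust variance model, chosen after seeing the data, it was 0.000758 (limma), and over all the alternatives run it ranged from 0.000758 to 1. Col3a1 was read through its only named probe set.

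No other gene named by rule passed in any setting, and the values that follow are those of genes chosen by smallest p in each direction, none of which passed (limma, adjusted p = 0.965 for each). On the higher side stood Gsta2, a glutathione S-transferase, with a log2 fold change of 0.91 (SE 0.164), and Gpc2, a glypican of the cell surface, with 1.15 (SE 0.229). Cyp2c68, a cytochrome P450, had a log2 fold change of 1.08 (SE 0.219). Tro, which encodes the adhesion protein trophinin, had 1.01 (SE 0.221), and the transglutaminase gene Tgm1 had 0.90 (SE 0.217). The values of Zfp169, Tomm20l, Il6ra, Fhod1, Smoc2 and Ang3 lay between 0.57 for Smoc2 and 0.71 for Tomm20l. The other probe set of Il6ra had 0.09 (SE 0.174). Of these 12 genes, 9 had a mean level under the median probe set's level of 5.23, where small differences in signal make large differences in log2. The control means of Cyp2c68, Zfp169, Tro, Tomm20l, Tgm1, Smoc2 and Ang3 lay under 3.62, the level below which probe sets were left out, so their folds are measured against a signal not shown to be above background.

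On the lower side, the channel gene Hcn3 had a log2 fold change of -1.70 (SE 0.261), from 4.75 ± 0.31 to 3.05 ± 0.44 (SD, n = 3). The chemokine gene Cxcl15 had -1.02 (SE 0.251). The brightest of the 12 were Mrpl32, which encodes a protein of the large mitochondrial ribosomal subunit, and Ostm1, whose product is the beta subunit of a lysosomal chloride transporter. Mrpl32 stood at 9.81 ± 0.13 in the controls and 9.06 ± 0.05 after mrhl siRNA (SD, n = 3), a log2 fold change of -0.75 (SE 0.139). Ostm1 stood at 9.08 ± 0.08 and 8.33 ± 0.11 (SD, n = 3), also a log2 fold change of -0.75 (SE 0.139). The glutamate receptor gene Grm4 had -0.85 (SE 0.154), and Elmod1 had -0.82 (SE 0.156). The kinase gene Wnk3, the phosphatase gene Cdc14a, Tcaf2, Akain1, Gpr155 and Icam5 lay between -0.69 for Wnk3 and -0.58 for Icam5. Other probe sets of Cdc14a had -0.04 and 0.12. Of these 12 genes, 7 had a mean level under that of the median probe set. The means of Hcn3, Grm4, Elmod1 and Tcaf2 after mrhl siRNA lay under 3.62, not shown to be above background.

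**Figure D1:**
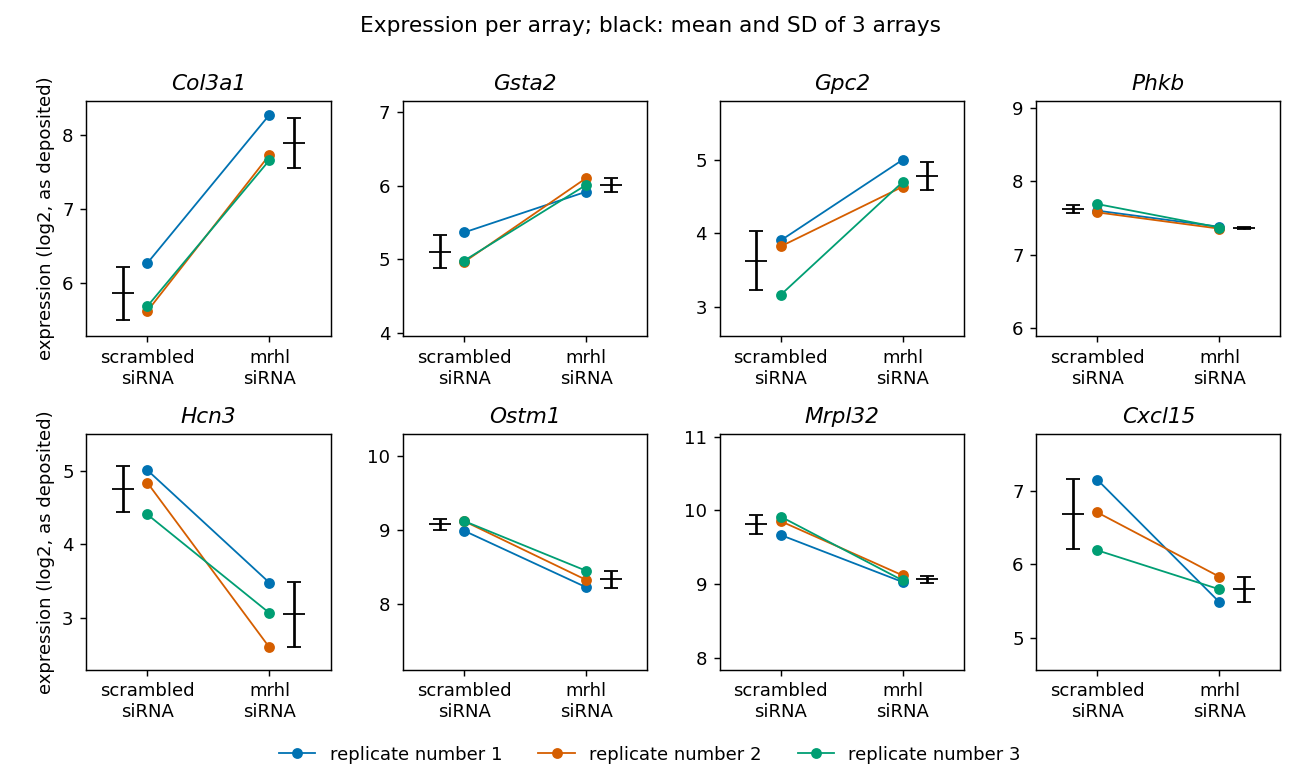
Deposited log2 expression (vertical axes, each spanning the same range) of 8 genes in the 3 scrambled siRNA and 3 mrhl siRNA arrays. Points are arrays, lines join arrays of equal replicate number, and black bars give the mean and SD of each group; the Col3a1 means are 5.85 and 7.89, and those of Phkb are 7.62 and 7.37.

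Over all 33778 probe sets tested, 0 passed an adjusted p of 0.05 in limma, so 0 of the 14885 genes passed with or without a 1.5-fold minimum. The smallest adjusted p was 0.965 (limma), and 1163 probe sets, 425 higher and 738 lower after mrhl siRNA, had an unadjusted p under 0.05 (1163 is 3.44%). Chance gives 5% without pair effects. On simulated arrays with pair effects, 1.29% of unchanged probe sets came under 0.05 in the unblocked fit. Those pair effects were fitted estimates that hold noise of their own, so 1.29% may be too low for these arrays. With the replicate number as a block, 0 probe sets passed again (limma, smallest adjusted p = 0.213) and 3411 had an unadjusted p under 0.05, 1307 higher and 2104 lower. That is 10.1%, where 5.07% of unchanged probe sets came under 0.05 in the blocked fit of the simulated arrays with pair effects. The simulation drew noise independently for each probe set, so neither simulated share gives the range that a count can take by chance. Without scrambled siRNA replicate 1, mrhl siRNA replicate 2 or mrhl siRNA replicate 3, the unblocked count of 1163 became 1832, 674 and 2406. A pooled-variance test per probe set without a shared spread passed 1 probe set, of Nkapd1, with a log2 fold change of -0.50 (adjusted p = 0.0191 after Benjamini-Hochberg), which was named after its value was seen. The groups did not overlap in 2839 probe sets, or 8.41%. Chance gives 10% where arrays are interchangeable, and the 3 other splits of the arrays that part all pairs gave 1306, 1325 and 1534. Of the 2839, 872 were higher and 1967 lower. At least 1.5-fold differences were found in 314 of them, 139 higher and 175 lower, and at least 2-fold differences in 27, 17 higher and 10 lower. On those simulated arrays, of 33778 probe sets, the unblocked fit recovered 74% of 4-fold changes and 3% of 2-fold changes. Those arrays held 100 changes of each size. The adjustment is stricter where fewer probe sets change, so these shares do not give the recovery when only a few genes change.

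None of the fixed genes of RNA helicases and Wnt signalling passed. The RNA helicase gene Ddx5 had a log2 fold change of -0.03 (95% interval -0.35 to 0.29) and its paralog Ddx17 had -0.03 (95% interval -0.36 to 0.30). Ctnnb1, which encodes beta-catenin, had -0.15 (95% interval -0.47 to 0.18). The beta-catenin targets Ccnd1 and Myc had -0.23 (SE 0.228) and -0.12 (SE 0.178). Axin2, a feedback target of the pathway, had 0.24 with an SE of 0.529, because both arrays of replicate number 1 stood at 8.78 and 8.93 and the other 4 between 7.15 and 7.83. The fixed gene Sox8 had no tested probe set paired with it alone.

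None of the 4 Wnt lists passed (limma camera, adjusted p = 0.398 for receptors and for antagonists, 0.453 for beta-catenin targets and 0.844 for ligands). Among 36 tested receptors and transducers, 20 had positive and 16 negative log2 fold changes, with a mean of 0.05; the receptor Fzd6 had -0.38 (SE 0.157) and the cofactor Bcl9l 0.35 (SE 0.173). Among 23 antagonists the mean was 0.04, with 0.37 (SE 0.149) for the Dkk1 receptor Kremen1 and 0.48 (SE 0.171) for Cxxc4, whose other probe set had -0.57. Among 21 Wnt ligands the mean was -0.016, with 0.54 (SE 0.313) for Wnt4, whose other probe set had 0.0032. Wnt8a had -0.33 (SE 0.20), at dim log2 levels of 3.95 in the controls and 3.63 after mrhl siRNA. Among 30 beta-catenin targets the mean was 0.04, with 0.76 (SE 0.314) for Fgf18 and 0.32 (SE 0.157) for Jun, whose other probe set had -0.13.

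Genes of the extracellular matrix gave the smallest p of any list by camera at its preset correlation without a block. With the replicate block that list was the unfolded protein and integrated stress response (limma camera, adjusted p = 0.134, against 0.266 for the matrix), and by fry without a block all lists had an adjusted p of 0.916 or more (limma). Of 46 tested members, 30 had positive and 16 negative log2 fold changes, with a median of 0.09 and a mean of 0.08, and the list did not pass (limma camera, adjusted p = 0.184). With an estimated correlation the adjusted p was 0.99 (limma camera). Adjusted over the list alone, 1 member passed, Col3a1, against 0 over all probe sets tested. Col3a1, at 2.04, lay far above the list's mean, and the list was not tested without it. The matrix inhibitor of calcification Mgp had -0.64 (SE 0.160). The mean of the list was -0.06 in the pair of number 1, 0.22 in that of number 2 and 0.08 in that of number 3. It passed without scrambled siRNA replicate 3 (limma camera, adjusted p = 0.0022) and without mrhl siRNA replicate 1 (adjusted p = 0.0156), but with an estimated correlation those values were 0.979 and 0.957. In a fit with the replicate block, fry's test for change in either direction, added after seeing the data, passed this list and the immediate early genes (limma fry, adjusted p = 0.0257 for each).

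The cell adhesion lists did not pass either. The 28 cadherins and protocadherins had a mean log2 fold change of 0.09 (limma camera, adjusted p = 0.297), with 18 positive and 10 negative. Within it Cdh11 had -0.56 (SE 0.235) and Ctnna2, which encodes an alpha-catenin, -0.38 (SE 0.157). The 32 integrins and immunoglobulin adhesion molecules had a mean of 0.07 (limma camera, adjusted p = 0.304). The fibronectin receptor subunit Itga5 had 0.87 (SE 0.420) and Alcam had -0.52 (SE 0.198).

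Germ cell genes showed no list past the test. The 18 tested genes of undifferentiated spermatogonia had a mean log2 fold change of 0.0084 (limma camera, adjusted p = 0.663), with 0.25 (SE 0.234) for Tspan8 and 0.22 (SE 0.204) for Cdh1. The 13 genes of differentiating spermatogonia had a mean of -0.014 (limma camera, adjusted p = 0.844), with 0.49 (SE 0.194) for the retinoic acid receptor Rarg and -0.37 (SE 0.195) for the methyltransferase Dnmt3b. Of 30 meiotic genes on the array only 13 were bright enough to be tested, with a mean of -0.11 (limma camera, adjusted p = 0.737). The synaptonemal complex genes Sycp3 and Syce2 had -0.52 (SE 0.193) and 0.42 (SE 0.180). Syce2 stood at 3.65 in the controls, close to 3.62, the level below which probe sets were left out. The 19 spermatid genes had a mean of 0.00023 (limma camera, adjusted p = 0.737), with -0.37 (SE 0.148) for the transcription factor gene Crem and 0.45 (SE 0.236) for the acrosomal gene Acrv1. Only 3 of the 13 meiotic and 6 of the 19 spermatid genes lay above the median probe set's level of 5.23. Of the undifferentiated and differentiating genes, 11 of 18 and 5 of 13 did. Both group means of Sycp3, Syce2, Crem, Acrv1 and Cdh1 lay under that level, where small differences in signal make large differences in log2.

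Markers of other cells of the testis gave no call. The 14 Sertoli cell markers had a mean log2 fold change of -0.07 (limma camera, adjusted p = 0.844), with -0.63 (SE 0.252) for Dhh and -0.37 (SE 0.204) for Gdnf. The 8 Leydig cell markers had a mean of -0.0089 (limma camera, adjusted p = 0.844), with -0.38 (SE 0.227) for Hsd11b1 and -0.29 (SE 0.187) for Hsd17b3. The 14 peritubular myoid and fibroblast markers had a mean of 0.05 (limma camera, adjusted p = 0.398), with 0.23 (SE 0.141) for S100a4 and 0.37 (SE 0.283) for Acta2. The 11 blood cell and endothelial markers had a mean of -0.04 (limma camera, adjusted p = 1), with -0.37 (SE 0.151) for Cd14 and -0.29 (SE 0.264) for Kdr.

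Genes of the interferon response, which double-stranded RNA can induce, did not pass as a list (limma camera, adjusted p = 0.663). Both groups received siRNA and no untransfected cells were measured, so a response shared by both groups would not show. The mean log2 level of the list was 9.44, and 34 of its 35 members lay above the median probe set's level. Of 35 members 12 had positive and 23 negative log2 fold changes, with a mean of -0.11, and Ifit2 had -0.62 (SE 0.208) and Cxcl10 -0.48 (SE 0.171). The 23 inflammatory and NF-kappaB genes had a mean of -0.11 (limma camera, adjusted p = 0.453), with -0.36 (SE 0.155) for the chemokine gene Ccl2 and -0.56 (SE 0.252) for Ccl7. The 31 genes of the unfolded protein and integrated stress response had the lowest mean of any list, -0.15, with 5 positive and 26 negative (limma camera, adjusted p = 0.304, and 0.99 with an estimated correlation). Within it Trib3 had -0.79 (SE 0.382) and Ddit3 -0.39 (SE 0.261), while a dimmer probe set of Ddit3 had 1.04 (SE 0.815). The 13 heat shock genes had a mean of -0.04 (limma camera, adjusted p = 1), with -0.20 (SE 0.156) for Dnaja1 and -0.22 (SE 0.203) for Hspa1b.

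Cell cycle genes did not pass as lists, and their pairs lay on both sides of 0. In the pair of number 1 the mean log2 fold change was 0.016 for G1/S and DNA replication and 0.08 for G2/M and mitosis. It was -0.17 and -0.24 in the pair of number 2, and -0.06 and -0.08 in that of number 3. Most probe sets tested, 18968 of 33778, had negative values. Of 39 genes of G1/S and DNA replication 31 had negative log2 fold changes, with a mean of -0.07 (limma camera, adjusted p = 0.542), and Cdk6 had -0.30 (SE 0.170) and Ccne1 -0.28 (SE 0.163). Of 39 genes of G2/M and mitosis 28 were negative, with a mean of -0.08 (limma camera, adjusted p = 0.398), and the spindle gene Prc1 had -0.37 (SE 0.174) and the condensin gene Smc2 -0.32 (SE 0.166). The 24 p53 targets had a mean of -0.09 (limma camera, adjusted p = 0.663), with 0.47 (SE 0.224) for Fbxo32 and -0.30 (SE 0.157) for Trp53inp1. The 29 immediate early genes had a mean of -0.06 (limma camera, adjusted p = 0.955), with 0.54 (SE 0.186) for Jund, whose dimmer probe set had -0.25. The 30 genes of the TGF-beta and BMP response had a mean of -0.06 (limma camera, adjusted p = 0.844), with -0.30 (SE 0.140) for the receptor Bmpr2 and -0.33 (SE 0.180) for Skil.

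Metabolic and ribosomal lists did not pass (limma camera, adjusted p = 0.904 for cholesterol synthesis, 0.398 for oxidative phosphorylation, 0.844 for glycolysis and hypoxia and 0.782 for ribosomal proteins). The means were -0.08 for 20 cholesterol synthesis genes, 0.02 for 45 oxidative phosphorylation genes, -0.06 for 29 glycolysis and hypoxia genes and -0.0090 for 37 cytosolic ribosomal protein genes. Srebf2, the master regulator of sterol synthesis, had 0.41 (SE 0.244) and the mevalonate pathway enzyme gene Mvd 0.33 (SE 0.153). Ndufa10 had 0.28 (SE 0.149), Atp5c1 -0.18 (SE 0.136), the phosphofructokinase gene Pfkp -0.19 (SE 0.156), Pfkfb3 -0.19 (SE 0.153), Rplp2 0.14 (SE 0.141) and Rpl12 -0.17 (SE 0.189).

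The remaining lists did not pass. The 12 phosphorylase kinase and glycogen genes had a mean log2 fold change of -0.09 (limma camera, adjusted p = 0.576), with -0.39 (SE 0.187) for the kinase's alpha subunit gene Phka1. The 17 small RNA and microprocessor factors had a mean of -0.05 (limma camera, adjusted p = 0.83), with -0.47 (SE 0.246) for Ago3, whose other probe sets had -0.19, -0.09 and 0.48, and -0.31 (SE 0.128) for Tnrc6b, whose other probe sets had 0.28 and -0.18. The 13 Sox factors had a mean of 0.09 (limma camera, adjusted p = 0.304), with 0.40 (SE 0.308) for Sox5, whose other probe sets had -0.29, -0.16 and 0.027, and 0.31 (SE 0.263) for Sox13. The 25 imprinted genes had a mean of 0.0094 (limma camera, adjusted p = 0.83), with -0.41 (SE 0.152) for Plagl1 and -0.54 (SE 0.20) for Magel2. Only 2 replication-dependent histone genes were tested, too few for a list: H2bc21 had -0.42 (SE 0.25) and H1f2 -0.14 (SE 0.233).

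**Figure D2:**
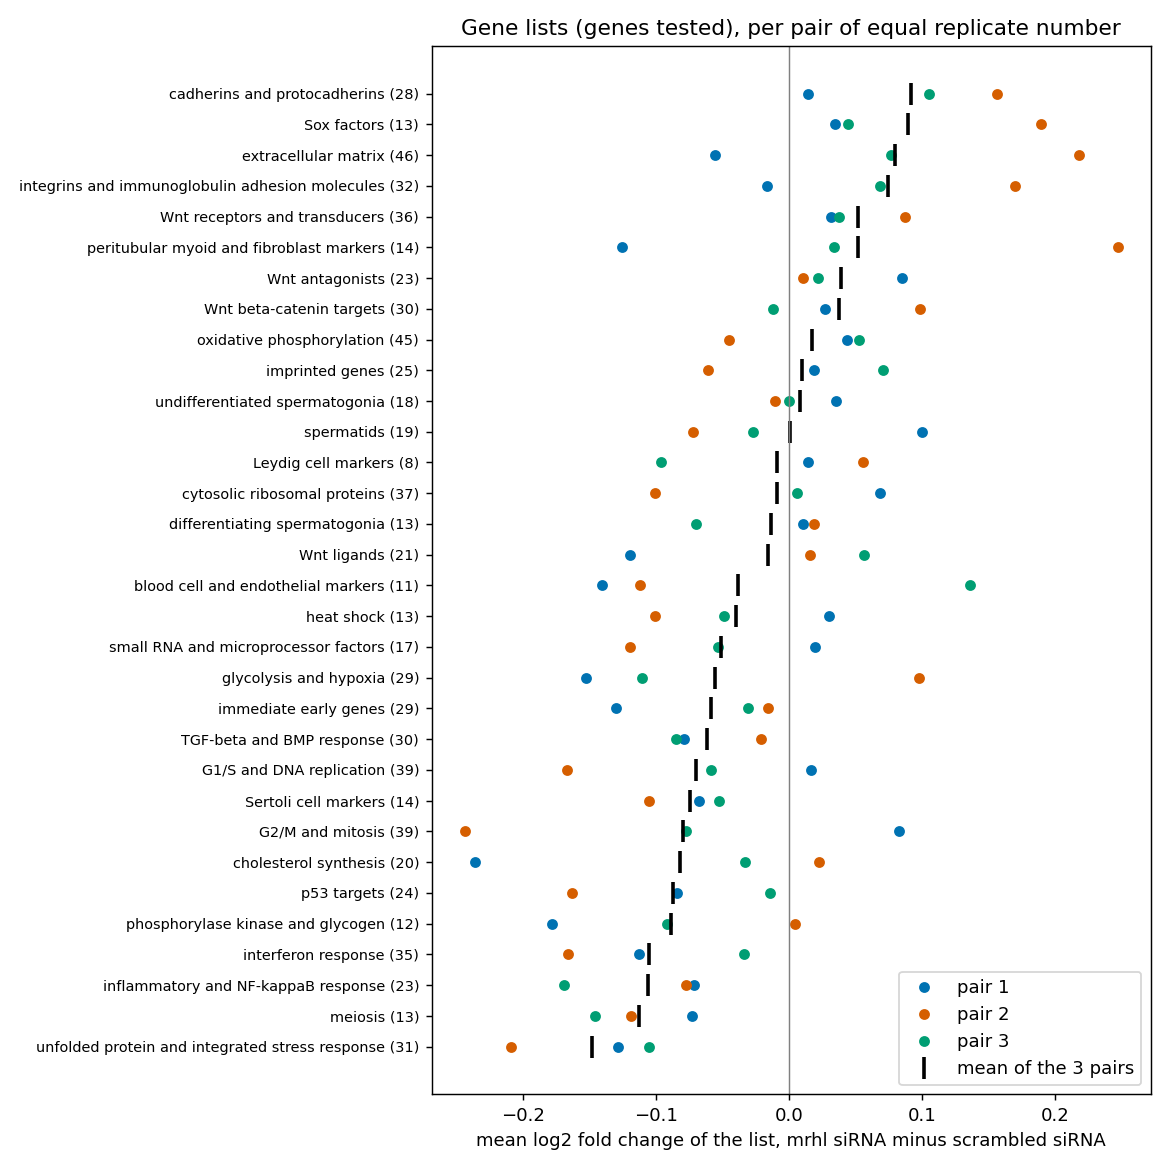
Mean log2 fold change (horizontal axis, mrhl siRNA minus scrambled siRNA) of each of the 32 gene lists tested, with the number of genes in brackets. Coloured points are the 3 pairs of arrays of equal replicate number and black ticks their mean; the mean runs from -0.15 for the unfolded protein and integrated stress response to 0.09 for the cadherins and protocadherins, and pairs often lie on both sides of 0.

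Over the 32 lists tested, 0 passed by camera, by camera with an estimated correlation and by fry, with smallest adjusted p of 0.184, 0.99 and 0.916 (limma), and 5 lists had an unadjusted camera p under 0.05. With the replicate block the smallest adjusted p was 0.134 by camera and 0.166 by fry (limma). Over all lists, 0 members passed over all probe sets tested, and 1, Col3a1, passed when adjusted over a list alone. The median log2 fold change over genes was -0.04, and camera sets a list against the other genes. Its direction was up, while the mean was negative, for the Wnt ligands, the differentiating spermatogonia, the Leydig, blood and endothelial markers, the cholesterol synthesis genes and the ribosomal proteins. For the spermatid genes the mean was positive and the median negative. Further named genes had other probe sets on the opposite side of 0: Smc2 at 0.30 and 0.21, Pfkp at 0.17, Bmpr2 at 0.13, Cdk6 at 0.10, Ddx5 at 0.09 and 0.0028, Ddx17 at 0.036, Ccnd1 at 0.028, Pfkfb3 at 0.028, Fbxo32 at -0.013, Tspan8 at -0.06 and Bcl9l at -0.09. Some named genes had other probe sets on the same side but close to 0, such as Dhh at -0.019, Acta2 at 0.031, Trp53inp1 at -0.034, Ndufa10 at 0.060 and Mvd at 0.078. With quantile normalization the means of the Wnt ligands, the differentiating spermatogonia, the Leydig markers and the ribosomal proteins were positive.

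Array quality was compared by group through the control rows. The 18S ribosomal RNA rows had a log2 mean of 5.26 ± 1.39 (SD, n = 3) in the controls and 4.17 ± 1.34 (SD, n = 3) after mrhl siRNA (two-sided exact permutation p = 0.3). The hybridization spike-ins had 9.35 ± 0.27 and 9.63 ± 0.14 (SD, n = 3; two-sided exact permutation p = 0.3). The 3'-minus-5' log2 difference of actin was 0.51 ± 0.11 and 0.42 ± 0.03 (SD, n = 3; two-sided exact permutation p = 0.2). The smallest p that 3 arrays against 3 allow is 0.1. The poly-A spike-in rows separated the replicate numbers, not the groups, at 4.30 and 4.42 in both arrays of number 1 and 7.42 to 8.38 in the other 4.

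**Figure D3:**
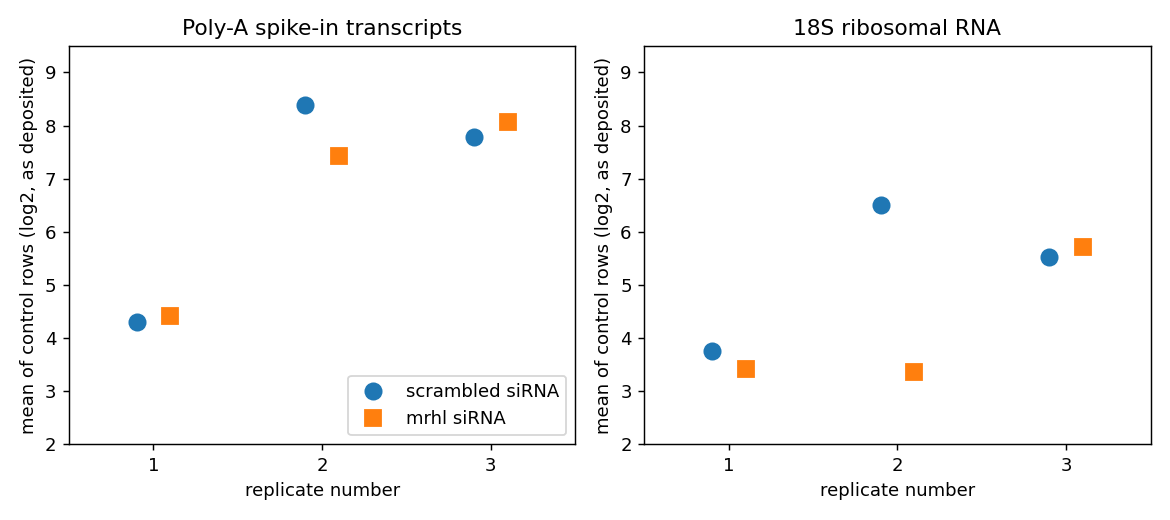
Mean log2 signal of the poly-A spike-in rows (left) and 18S ribosomal RNA rows (right) against replicate number, with circles for scrambled siRNA and squares for mrhl siRNA arrays. Both number 1 arrays lie at 4.30 and 4.42 for the spike-ins, and mrhl siRNA replicate 2 lies at 3.37 for 18S while scrambled siRNA replicate 2 lies at 6.50.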

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

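Of 1943 single-gene values under the alternatives, 1928 kept their sign and did not pass; the settings named as added were chosen after seeing the data. Col3a1 lay between 1.31 and 2.25. Probe sets past the threshold numbered 0 under 18 of 21 alternatives (limma), 2 in the added fits of the replicate block with trend and robust and of the replicate block with offset 64, and 1 in the pooled-variance test. Genes past it, with or without the 1.5-fold minimum, numbered 1 in each of those 2 block fits, Col3a1 (limma, adjusted p = 0.000758 and 0.00597). The other probe set there belonged to Smarca4, named after its values were seen, at 1.20 (limma, adjusted p = 0.0445) and 0.80 (limma, adjusted p = 0.0492), while a brighter Smarca4 probe set had 0.17. The replicate block alone changed no call of a probe set or gene, and of the list tests only fry in either direction.

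At an unadjusted p under 0.05, the count of 1163 became 1758 without the filter, which tests more probe sets, 2132 with array weights, 3411 with the replicate block, 4411 with block, trend and robust, 4688 with block and offset 64, and 674 to 2406 with an array left out. Lists past the threshold numbered 0 to 1 with an array left out, 2 with both number 1 arrays left out (limma camera, adjusted p = 0.00611 for the extracellular matrix and 0.0185 for G2/M and mitosis, each 0.986 with an estimated correlation), and 2 with the replicate block and fry in either direction; over the other settings of camera the smallest adjusted p lay between 0.0689 and 0.99. Signs turned in 8 genes, in some of them far from 0. With an array left out, Ddx5 ran from -0.077 to 0.026, Ddx17 from -0.080 to 0.030, Myc from -0.24 to 0.00069, Axin2 from -0.22 to 0.73 and H1f2 from -0.29 to 0.066. With the 18S covariate, Axin2 had -0.35 and Ddx17 0.032. With the mean of a gene's probe sets, Ddx17 had 0.0042, Cxxc4 -0.041, Ddit3 0.33 and Sox5 -0.0063. Beyond the construction of each setting, the cause was not tested.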

Other observations

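The contrasts and tests of this part were chosen after the results were seen, except the counts over other splits of the arrays for adjusted p, which were planned. Of 35 interferon response genes, the median log2 difference was -0.22 between number 1 and the other numbers and -0.11 between mrhl siRNA and scrambled siRNA. In the 2 arrays of number 1, Oasl1, an oligoadenylate synthetase-like gene, had a log2 level of 8.30 ± 0.10, against 10.29 ± 0.22 in the 4 arrays of numbers 2 and 3 (SD). The antiviral genes Ifit3, Rsad2 and Mx2 stood at 9.55 against 10.70, 9.07 against 10.41 and 7.56 against 8.40. As a list they were lower in number 1 (limma camera, adjusted p = 1.46e-06), and 7 members passed when adjusted over the list alone. With an estimated correlation the list did not pass (limma camera, adjusted p = 0.563). That correlation was only 0.0401, so the lost call does not by itself show strongly correlated members. Over all probe sets 0 passed (limma) and 5150 had an unadjusted p under 0.05. This contrast counts the 2 arrays of number 1 as independent replicates, although equal numbers were read as pairs. Number 1 is then a single experiment, so the p-values and counts of this contrast, here and in the next paragraph, do not measure the spread between experiments.

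In the same contrast the Wnt ligands were higher in number 1 (limma camera, adjusted p = 0.00885, and 0.563 with an estimated correlation), with 3 of 21 members past the threshold over the list alone. Their correlation was estimated at -0.0323, below the preset 0.01, so a higher correlation does not account for the larger adjusted p. Wnt10a stood at 8.93 against 7.86 and Wnt6 at 8.08 against 6.99. The beta-catenin targets did not pass (limma camera, adjusted p = 0.72): Axin2 stood at 8.86 against 7.42, and Sox9 at 6.61 against 7.47 and Ccnd2 at 9.59 against 10.46 lay the other way. The immediate early, cholesterol synthesis and stress response lists were lower in number 1 (limma camera, adjusted p = 0.00885, 0.0201 and 0.0205, each 0.996 with an estimated correlation). In the stress list 11 of 31 members passed over the list alone, among them the cystine transporter gene Slc7a11 at 4.90 against 5.88 and, in the opposite direction, the chaperone gene Pdia4 at 8.12 against 7.20.

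Arrays of equal replicate number had positively correlated deviations from their group means in all 3 pairs, but only weakly in number 2 (r = 0.201). Separate labelling batches are a candidate explanation for number 1: the poly-A spike-ins, which are added to the RNA before labelling, were 3.00 log2 units lower in the higher number 1 array than in the lowest of the others. Carry-over of 18S ribosomal RNA stays open: the lowest array of numbers 2 and 3 lay at -0.396 log2 units from the highest number 1 array, but this was mrhl siRNA replicate 2 alone, and the 18S means were alike in number 1 (3.76 and 3.42) and number 3 (5.52 and 5.72) and apart in number 2 (6.50 and 3.37), whose arrays correlated least. For number 1, separate cultures or transfection days cannot be told apart from labelling, since the spike-ins set the same 2 arrays apart. Numbers 2 (8.38 and 7.42) and 3 (7.79 and 8.07) overlapped in the spike-ins, which therefore do not show what the arrays of those numbers share. In the contrast of number 1 with the others, 0 single probe sets passed. No biological explanation was tested, since the design names no factor behind the numbers.

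For Col3a1, 4.11-fold higher after mrhl siRNA, a shift shared by both arrays of a number cancels, because each number holds 1 array of each group. The smallest difference within a pair was 1.99 log2 units, which is therefore no separate test of such a batch. RNA from fibroblasts cannot be told apart by the listed markers: of 13 fibroblast genes tested, only 2, Col6a3 and Fap, lay in the controls at or under the level Col3a1 reached, and their median log2 fold change was 0.20. Abundant fibroblast genes were already high in the controls, such as Col1a1 at 12.19 and Dcn at 12.67, with log2 fold changes of 0.31 and -0.09, and 13 of the 16 listed were also extracellular matrix genes. Hybridization that concerns its probe set only also stays open, with 1 named probe set tested. An effect of mrhl silencing, or of the siRNA on other RNAs, remains among the open explanations and was not tested.

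Of Phkb and its 5 nearest genes on either side that the array measured, 10 of 11 had negative log2 fold changes, from -0.40 for 4921524J17Rik to -0.02 for Gm10638, and N4bp1 had 0.16. The median was -0.15. A local shift around the silenced RNA's locus was tested against 14646 runs of 11 neighbouring genes: 11.2% had as low a median and 6.70% had as many negative genes, so the run does not stand out.

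The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05, and 6 of the 10 keep a pair together. For probe sets, genes and genes past 1.5-fold at an adjusted p of 0.05 (limma), all 10 splits gave as many as the real 0, and the highest of the others was 0. For gene lists all 10 gave as many as the real 0, and the highest other was 9. For probe sets at an unadjusted p under 0.05, 6 of 10 gave as many as the real 1163, with 7683 as the highest other, and for probe sets whose groups do not overlap, 5 of 10 gave as many as the real 2839, with 10092 as the highest other. Counts several times the real one point to a structure of the arrays other than the siRNA groups, though not one shown to be independent of the siRNA. The split with 7683 set scrambled siRNA replicates 2 and 3 and mrhl siRNA replicate 3, with 18S means of 5.52 or more, against the 3 arrays at 3.76 or less. Those 3 were both arrays of number 1 and mrhl siRNA replicate 2. Among the 7683 probe sets 5200 were higher and 2483 lower with high 18S (limma, smallest adjusted p = 0.102). Number 1 against the other numbers gave 5150 at an unadjusted p under 0.05 (limma). In this split 18S and number 1 cannot be told apart. The mean 18S level was also lower after mrhl siRNA, 4.17 against 5.26 in the controls, so 18S and siRNA are not fully apart. With 18S as a covariate the siRNA comparison gave 1664 at an unadjusted p and 0 past the adjusted threshold (limma).

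The real split parts all 3 pairs, as do 3 others. With the replicate block, the real split gave 3411 probe sets at an unadjusted p under 0.05 and the highest of the others 1210, so that 1 of the 4 gave as many. Without the block the 3 others gave 481, 468 and 535 against the real 1163, and 1306, 1325 and 1534 probe sets whose groups do not overlap against the real 2839. For gene lists the 3 others gave 0, 2 and 2 against the real 0. The real split was thus the highest of the 4 in the counts of probe sets and not in that of lists, and 4 splits are too few for a share under 0.05.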
